A study of Mus musculus with 8 samples.

How the data were processed

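RNA from mouse corneas was measured on 8 one-colour Affymetrix arrays with 45101 probe sets each. Per the labels, 4 arrays hold corneas of mice that overexpress TGF-beta (here TGFB) and 4 hold corneas of their wildtype littermates. Arrays are numbered 1 to 4 within a group in the order of their records, and the numbers pair no arrays. The extraction reagent is named as TRizol, per the labels' titles.

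The deposited table holds linear probe set intensities that are never negative. The tool and scaling that made the deposited intensities are not given in the sources used here. The values themselves show a 2% trimmed mean of 150 on every array, as global scaling to a common target gives. Median signals ran from 26.3 to 34.4, and between 34.9% and 40.9% of probe sets lay below a signal of 16 on an array. The number of arrays limits the precision. No 2 arrays shared identical values.

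Because the trimmed means were equal, no further normalization between arrays was applied. Values were taken as log2(signal + 16), so a difference between groups is on that scale and understates the change of dim genes. The 64 control probe sets were left out of the tests. A platform annotation of 2016 gave 1 gene symbol to 34945 probe sets and several to 932, and 9160 probe sets were not named here. Of the probe sets with 1 symbol, 34741 were matched by Entrez ID to a RefSeq gene table of assembly GRCm38.p6, which gave the current symbol and which genes neighbour each other. No coordinates were used otherwise. Each gene was represented by the probe set with the highest mean over the 8 arrays, with groups ignored, which left 18193 genes. Probe sets of other genes were not analysed here at the gene level.

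The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, 9.03 total degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p under 0.05. Differences are TGFB minus wildtype, with the moderated standard error (SE). Shifts of 31 gene lists with 878 entries were tested with camera at a preset correlation of 0.01, adjusted over the lists. Of 832 distinct list genes, 754 were measured. Camera with an estimated correlation, fry and an exact two-sided permutation test of the list mean over the 70 assignments of arrays stand beside it. Fry is a rotation test of whether the members of a list shift together, without reference to the genes outside it. Members of each list were also adjusted over the list alone. The separation of the arrays was described by principal components, tested in the same exact way.

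The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names Tgfb1, Tgfb2 and Tgfb3 first. It then takes up to 12 genes per direction past the threshold, or the 8 with the smallest p as values only where fewer than 5 pass. It adds up to 4 members with the smallest p in each list, and 10 corneal stroma, epithelium and scar genes whatever their values: Kera, Lum, Dcn, Krt12, Aldh3a1, Acta2, Col1a1, Col3a1, Fn1 and Tgfbi. Genes named outside this rule were chosen after their values were seen, and each is marked so.

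The alternatives were offsets of 1 and 32, quantile normalization, median centring, a filter at the 40th percentile of probe set means, the mean of all probe sets of a gene, every probe set as its own unit, a variance trend, robust eBayes, array weights, stricter thresholds, camera with an estimated correlation, and leaving out each array in turn. Alternatives added after the data were seen use a cornified epidermis score (the mean of 7 genes: Krt1, Krt10, Flg, Ivl, Lor, Krtdap and Sbsn), the lens list mean or the pigment list mean as a covariate, or leave out arrays with signs of other tissue or of RNA decay. Counts at an unadjusted p under each alternative were also added then.

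The limma step was tested on simulated data with the real means and spreads of the 18193 genes and 200 changed genes, in 10 simulations. For this comparison of 4 against 4 arrays it recovered 50.0% of 2-fold changes, 87.3% of 4-fold changes and 95.8% of 8-fold changes, and 4.54% of its calls were false. These rates are over the simulated changed genes as a set, with no separate rate by brightness. They need not hold for dim genes, whose change the log2 scale used here understates. Camera recovered a list shift of 0.5 (log2) in 10 of 10 simulations. The simulated arrays vary independently from gene to gene, which the real arrays do not. Figures were drawn with matplotlib.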

Results

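The series profiled corneas of mice that overexpress TGF-beta and of their wildtype littermates, with 4 arrays per group. TGF-beta is a secreted growth factor that drives matrix production and myofibroblast formation in wound healing. The labels do not name the TGF-beta isoform, the promoter, the tissue that makes it or the age of the mice. They also do not say that each array holds a separate animal, so p-values measure only the spread between these arrays, which may be technical. The comparison asks which corneal transcripts differ between the groups. After selection of 1 probe set per gene, 18193 genes were compared. Values below are log2(signal + 16) unless called signals, and means are given ± SD over the 4 arrays of a group.

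The arrays held transcripts of several tissues next to the cornea, in amounts that did not follow the groups alone. Krt10, a keratin of cornified skin, had signals of 11198 and 10154 in TGFB 1 and TGFB 2 and of 8494 in wildtype 2, against 139.8 to 409 in the other arrays. The mean of 7 cornified epidermis genes was 9.50 ± 3.36 in TGFB and 7.84 ± 2.44 in wildtype arrays (exact permutation p = 0.286). The lens crystallin Cryga ran from a signal of 10.9 in TGFB 1 to 6313 in wildtype 3. Acta1, the actin of skeletal muscle, reached 5613 to 8340 on every array. These 3 marker genes were chosen after their values were seen. The 3'/5' signal ratio of Gapdh, which grows with RNA decay, was 6.41 in wildtype 4 and between 2.19 and 4.31 elsewhere. Wildtype 4 also differed in corneal markers. Its corneal epithelial list mean was 8.38, against 9.33 to 9.61 in the other wildtype arrays and 9.02 to 9.48 in TGFB arrays. Its Krt12 signal was 562, against 3008 to 5766 in the other wildtype arrays, though TGFB 1 had 289. Its Kera signal was 8110, against 2073 to 4329 elsewhere. The first principal component carried 42.7% of the variance and did not part the groups (exact two-sided permutation p = 0.371, where 0.0286 is the smallest possible). It parted the arrays with high Krt10, TGFB 1, TGFB 2 and wildtype 2 (-48.4, -65.6 and -24.6), from the others (20.4 to 31.3). On average TGFB 3, TGFB 4, wildtype 2 and wildtype 4 correlated more with the other group than with their own. For TGFB 1, TGFB 2, wildtype 1 and wildtype 3 the reverse held. The array closest to wildtype 2 was TGFB 1 (r = 0.973), and the array closest to wildtype 4 was TGFB 4 (r = 0.975). Correlations between arrays ran from 0.919 to 0.986 across genes, which are not independent replicates.

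**Figure D1:**
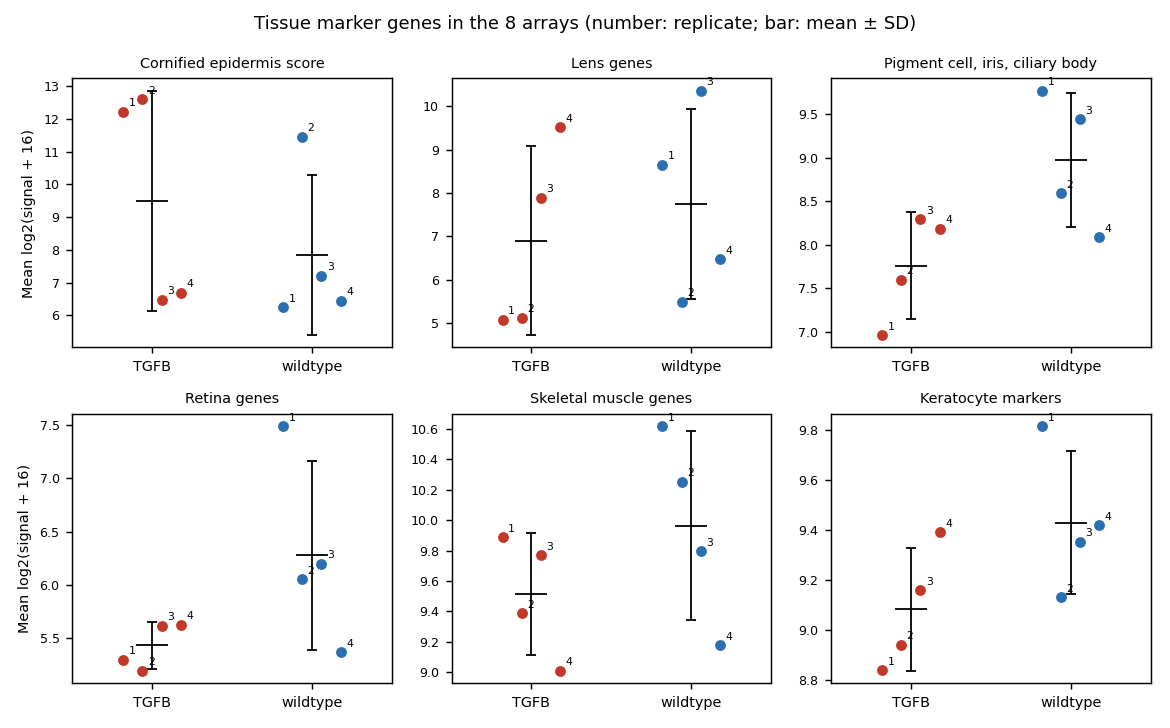
Mean log2(signal + 16) of tissue marker genes in each array (points, numbered by replicate) for the TGFB and wildtype groups, with group mean ± SD (bars). TGFB 1, TGFB 2 and wildtype 2 hold the high cornified epidermis scores (12.22, 12.59 and 11.45), and lens transcripts range from 5.08 to 10.36.

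None of the TGF-beta genes themselves differed past the threshold, though the SEs leave room for a rise. Tgfb1 was dim, with signals of 32.4, 29.0, 50.5 and 61.2 in the TGFB arrays and 35.1, 19.6, 19.9 and 47.7 in the wildtype arrays. Its log2 difference was 0.36 (SE 0.25, limma adjusted p = 0.817), while a second, dimmer Tgfb1 probe set gave -0.25 (SE 0.25). Tgfb2 was brighter, with signals of 801, 420, 910 and 977 in TGFB and 837, 558, 958 and 899 in wildtype arrays, a log2 difference of -0.10 (SE 0.28, adjusted p = 0.963). The other Tgfb2 probe sets gave -0.22 (SE 0.47), -0.11 (SE 0.42) and -0.021 (SE 0.22). Tgfb3 gave signals of 508, 317, 539 and 509 against 568, 358, 245 and 660, a log2 difference of 0.10 (SE 0.31, adjusted p = 0.969). A transgene from another species, of an altered sequence or made outside the cornea need not be seen by these mouse probe sets, so these values check the labels only in part.

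Compared with wildtype corneas, TGFB corneas showed no single gene past the threshold, while lists of genes shifted in camera with a preset correlation. Pigment cell, iris and ciliary body genes were lower by a mean log2 difference of -1.21 (SE over arrays 0.49), and retina genes by -0.84 (SE 0.46). The list of conjunctival, stress and cornified keratinocyte markers was higher by 0.88 (SE 0.65), epithelial junction genes by 0.34 (SE 0.23), immediate-early genes by 0.37 (SE 0.11) and known TGF-beta target genes by 0.29 (SE 0.17). Myofibroblast genes and collagens, the classical scar genes, did not pass. None of these list shifts passed with an estimated correlation, where the smallest adjusted p over the 31 lists was 0.278.

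Limma called 0 genes higher and 0 genes lower at adjusted p under 0.05, and the smallest adjusted p was 0.623. At an unadjusted p under 0.05 there were 483 higher and 805 lower genes, 1288 in all, where 910 would come by chance. The groups did not overlap at all for 717 genes (3.94%, with 2.86% given by chance). Leaving out wildtype 4, the array with the high 3'/5' ratio, gave 0 higher and 2 lower genes, with 810 higher and 1497 lower at the unadjusted threshold. The 2 genes, chosen after their values were seen, were the carboxylesterase Ces1d (log2 difference of -3.25, adjusted p = 0.00217) and the peptidase inhibitor Pi16 (log2 difference of -3.08, adjusted p = 0.0450). With all 8 arrays their adjusted p was 0.623 and 0.650, and over the settings tried the smallest adjusted p of any gene ran from 0.00217 to 1.00. Wildtype 4 also stood apart in corneal epithelial and stromal markers, so changes seen without it cannot be tied to RNA decay alone.

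The 8 genes with the smallest p among those with higher means in TGFB corneas are given as values only, since none passed. They were the zinc finger gene Zfp52 (log2 difference of 0.79, SE 0.14), the cytochrome Cyp2c29 (0.94, SE 0.18), the keratinocyte 14-3-3 protein gene Sfn (1.24, SE 0.24), the laminin chain Lama3 (1.22, SE 0.24), Ly6g6d (0.73, SE 0.15), the early growth response factor Egr2 (1.37, SE 0.29), the potassium channel Kcnn4 (1.03, SE 0.23) and the acyl-CoA synthetase Acsl4 (0.78, SE 0.18). Among those with lower means stood the chemokine Ccl24 (-1.49, SE 0.24), the mitochondrial membrane protein gene Mpv17 (-1.01, SE 0.17), the ion channel Asic2 (-0.67, SE 0.12), B230217C12Rik (-0.91, SE 0.17), Ecrg4 (-1.65, SE 0.30), the reductase Akr1e1 (-1.01, SE 0.19), Plcxd3 (-1.54, SE 0.29) and the monooxygenase Fmo1 (-1.32, SE 0.25). The limma adjusted p was 0.623 for each of the 16 genes, and the groups did not overlap for any of them. Asic2, Cyp2c29, Ly6g6d and Ccl24 were dim, with mean values of 4.20, 4.34, 4.31 and 4.58 in the group with the lower mean. A second probe set of Mpv17 went the other way (0.73, SE 0.24).

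**Figure D2:**
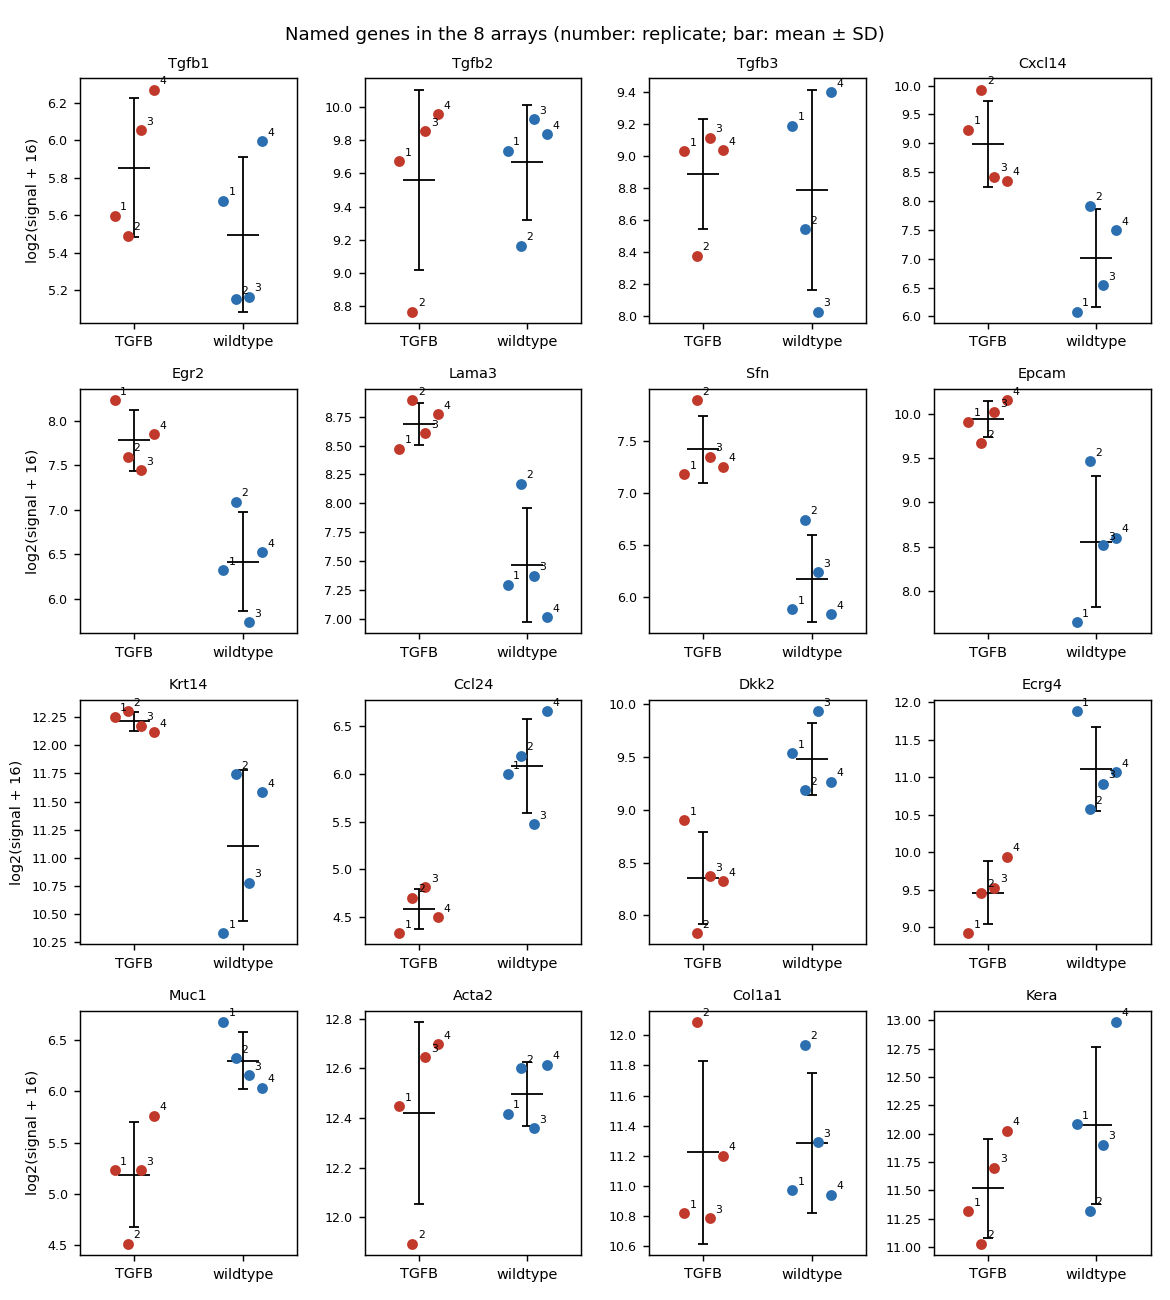
Log2(signal + 16) of 16 named genes in each array (points, numbered by replicate), with group mean ± SD (bars). Egr2, Lama3, Sfn, Epcam, Krt14 and Cxcl14 lie higher in all TGFB arrays and Ccl24, Dkk2, Ecrg4 and Muc1 lower, each without passing the adjusted test, while Tgfb1, Tgfb2, Tgfb3, Acta2, Col1a1 and Kera overlap.

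Of the 31 gene lists, 15 passed camera with the preset correlation, 6 higher and 9 lower, while 16 did not. With an estimated correlation 0 lists passed, with fry 0 and with the exact permutation test 0. The exact count decides little. Its smallest possible p is 0.0286, which after adjustment over 31 lists passes only if many lists reach it together. Camera with the preset correlation also called lists in every other split of the 8 arrays into 4 and 4, from 4 to 19. A call with the preset correlation alone is therefore weak evidence of a difference between the groups. No member of any list passed limma over all genes tested. Adjusted over the list alone, 8 genes in 5 lists passed and none in the other 26 lists. They were Lama3, the connexin Gjb2, Guca1a, Mlana, Oca2, Trpm1, Tyrp1 and Egr2. Without wildtype 4, 21 lists passed, and without wildtype 1, 9 did. In 9 other processing settings with the preset correlation, keratocyte, corneal endothelial and IGF and WNT genes kept their call in 3, skeletal muscle genes in 4, nerve genes in 5, interferon-response genes in 6, TGF-beta ligands in 7, and inflammatory, keratinocyte and junction genes in 8. With the pigment list mean as a covariate, a setting added after the data were seen, TGF-beta target genes (0.32, adjusted p = 0.0278) and immediate-early genes (0.26, adjusted p = 0.0138) kept their call, and the other 12 of the 14 called lists tested in it lost theirs. The pigment list mean itself differed between the groups by -1.21, so covariate and group cannot be cleanly parted in 8 arrays. A call lost or turned there does not show carried-over tissue as its cause.

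**Figure D3:**
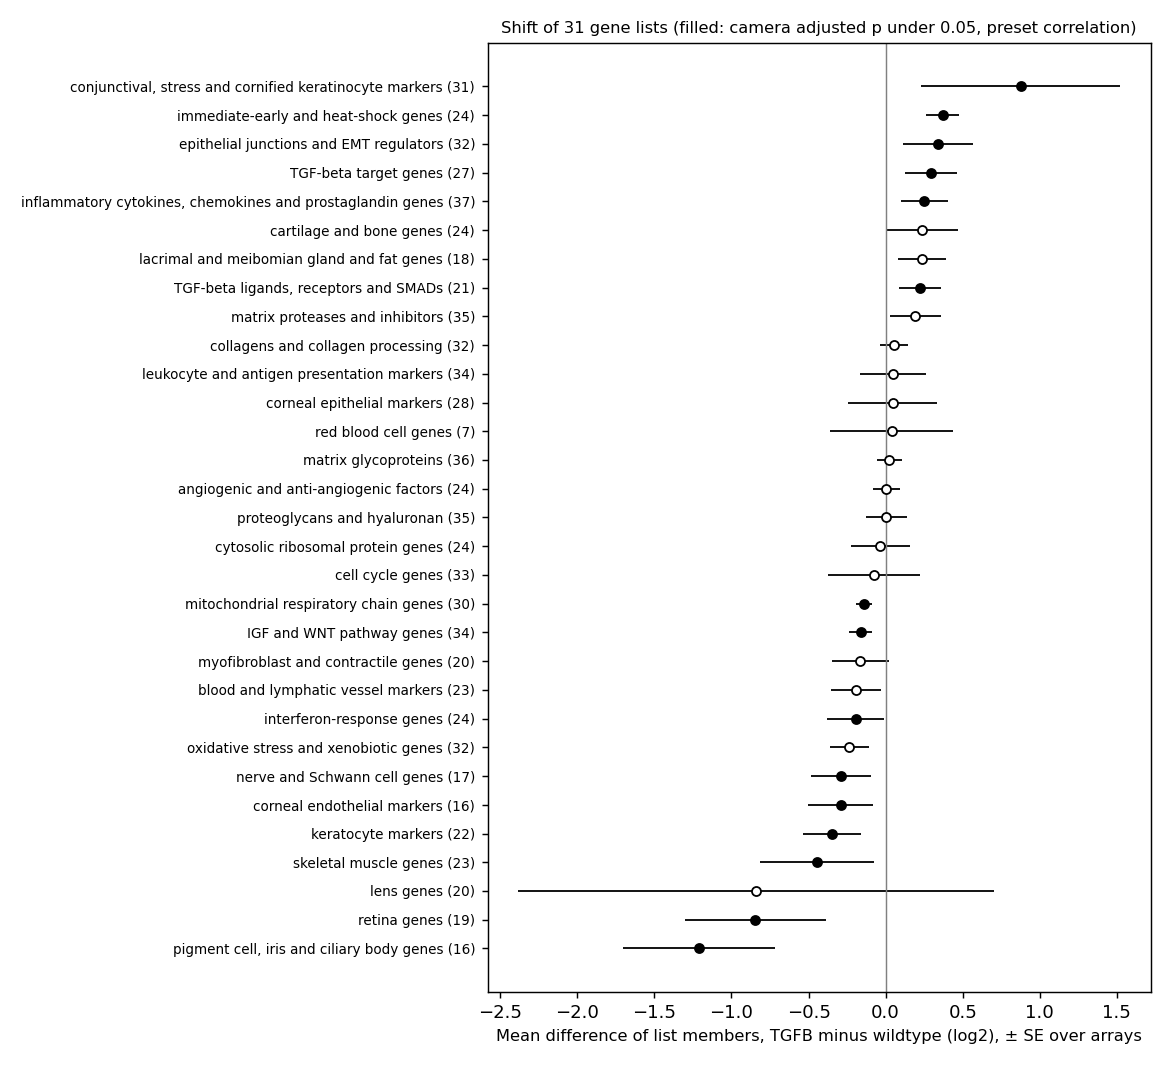
Mean log2 difference (TGFB minus wildtype) of the measured members of each of 31 gene lists, with the number of members in brackets and bars of ± 1 SE over arrays. Filled points passed camera at adjusted p under 0.05 with the preset correlation, from pigment cell genes at -1.21 to keratinocyte markers at 0.88, and none passed with an estimated correlation.

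The list of conjunctival, stress and cornified keratinocyte markers rose by a mean of 0.88 (camera adjusted p = 0.00105), with 24 of 31 members higher. This call was lost with an estimated correlation (adjusted p = 0.522 with an estimated correlation). Without TGFB 2 the shift was 0.58 (adjusted p = 0.00762). Without the 3 arrays with cornified transcripts it was 0.38 (adjusted p = 0.00642), below the 0.51 of TGF-beta target genes in that setting. Its members went both ways. Krt16, a keratin of wounded epithelium, had a log2 difference of 2.75 (SE 0.71), and the cornified envelope gene Sprr1a one of 1.79 (SE 0.58). The surface mucin Muc1 had -1.11 (SE 0.26) and the conjunctival keratin Krt4 -1.69 (SE 0.48). The limma adjusted p of these 4 genes lay between 0.623 and 0.661. The cornified epidermis score was high in TGFB 1, TGFB 2 and wildtype 2. Its 7 genes all belong to this list, so it moves with the list by construction. Epithelial junctions and EMT regulators rose by 0.34 (adjusted p = 0.00235, and adjusted p = 0.522 with an estimated correlation), with 23 of 32 members higher. The adhesion molecule Epcam had a difference of 1.38 (SE 0.33), the claudin Cldn1 0.81 (SE 0.24), E-cadherin Cdh1 0.84 (SE 0.27) and desmoplakin Dsp 0.90 (SE 0.31). Without wildtype 4 the junction shift was 0.21 (adjusted p = 0.0388). Both lists held their call without any single array and lost it with array weights (adjusted p = 0.0503 and 0.0951). Among settings added after the data were seen, both also lost it with the pigment list mean as a covariate (-0.11 and 0.20, adjusted p = 0.721 and 0.0655) and without wildtype 1 and wildtype 4 (0.36 and 0.059, adjusted p = 0.197 and 0.267).

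Corneal epithelial markers as a whole did not pass (mean 0.046, median 0.30, adjusted p = 0.112). Basal keratin Krt14 was 12.21 ± 0.08 in TGFB and 11.11 ± 0.67 in wildtype corneas, and the connexin Gjb2 had a difference of 1.48 (SE 0.34). Krt12, the keratin of differentiated corneal epithelium, was 11.05 ± 1.87 against 11.39 ± 1.53 (adjusted p = 0.966). The corneal crystallin Aldh3a1 was 6.53 ± 0.46 against 8.58 ± 2.41 (adjusted p = 0.734), and transketolase Tkt had a difference of -0.93 (SE 0.27). Over single arrays left out the list mean ran from -0.22 without wildtype 4 to 0.19 without wildtype 2, and was also below 0 without TGFB 2, so its sign is not settled. The list passed without TGFB 1 (0.12, adjusted p = 0.0406) or without wildtype 2 (adjusted p = 0.0120). Among the settings added later it passed with the pigment covariate (0.42, adjusted p = 0.00283) and without the 3 arrays with cornified transcripts (0.17, adjusted p = 0.00994).

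TGF-beta target genes rose as a list by 0.29, with 20 of 27 members higher and 7 lower (camera adjusted p = 0.00571). The call was lost with an estimated correlation (adjusted p = 0.522 with an estimated correlation) and without TGFB 4 (0.19, adjusted p = 0.102). Among the members, the matricellular protein tenascin C (Tnc) had a log2 difference of 1.28 (SE 0.41), the cell cycle inhibitor Cdkn1a 0.92 (SE 0.36), the growth factor Pdgfb 0.47 (SE 0.16) and Id3, which TGF-beta and BMP signals act on, -0.53 (SE 0.20). Tgfbi, an abundant corneal matrix protein, was 11.42 ± 0.77 against 11.20 ± 0.33 (adjusted p = 0.930). Ligands, receptors and SMADs rose by 0.22 (adjusted p = 0.0326, and adjusted p = 0.562 with an estimated correlation), with 14 of 21 members higher, among them follistatin Fst (1.38, SE 0.38), Ltbp1 (0.58, SE 0.20), Ltbp2 (1.05, SE 0.48) and Smad2 (0.45, SE 0.19). That call ended without TGFB 3, TGFB 4, wildtype 2 or wildtype 3 (adjusted p from 0.0621 to 0.175), and with the mean of all probe sets of a gene or every probe set as its own unit.

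Matrix and myofibroblast genes did not pass as groups. Myofibroblast and contractile genes had a mean difference of -0.16 (camera adjusted p = 0.748), with 7 of 20 members higher. That mean ran from -0.25 without TGFB 1 to -0.033 without TGFB 2, and from -0.22 to 0.019 over the other processing settings. Smooth muscle actin Acta2 was 12.42 ± 0.37 in TGFB and 12.50 ± 0.13 in wildtype corneas (adjusted p = 0.960). Palladin (Palld) had a difference of 0.74 (SE 0.24), Actn1 0.43 (SE 0.17), the smooth muscle calponin Cnn1 -1.40 (SE 0.54) and smooth muscle myosin Myh11 -1.78 (SE 0.82). Collagens and collagen processing gave 0.055 (adjusted p = 0.385), matrix glycoproteins 0.023 (adjusted p = 0.748), proteoglycans 0.0056 (adjusted p = 0.956) and matrix proteases 0.19 (adjusted p = 0.137). Col1a1 was 11.22 ± 0.61 against 11.29 ± 0.46, Col3a1 13.14 ± 0.13 against 13.24 ± 0.35 and fibronectin Fn1 12.42 ± 0.32 against 12.10 ± 0.70 (adjusted p = 0.984, 0.945 and 0.873). Laminin chains of basement membranes went both ways, with Lamb3 at 1.35 (SE 0.37) and Lama3 at 1.22 (SE 0.24), but Lama1 at -0.75 (SE 0.31) and Lamb1 at -0.59 (SE 0.28), the latter pair chosen after their values were seen. The anchoring fibril collagen Col7a1 had a difference of 0.73 (SE 0.24) and the microfibril gene Mfap5 -1.07 (SE 0.28). Mmp13 had a difference of 1.19 (SE 0.40), Mmp9 1.73 (SE 0.59), Serpinb2 2.29 (SE 0.87) and the protease inhibitor A2m -2.02 (SE 0.71). Over single arrays left out, collagens ran from 0.0049 without wildtype 3 and proteases from 0.097 without TGFB 4. Matrix glycoproteins ran from -0.021 to 0.081 and proteoglycans from -0.060 to 0.11, so the sign of both is not settled. Without wildtype 4, collagens (0.12, adjusted p = 0.0216) and proteases (0.30, adjusted p = 0.00784) passed, and proteases also without TGFB 2 (adjusted p = 0.00601) and with array weights (0.32, adjusted p = 0.00380). Of the settings added later, proteases passed with the cornified score as a covariate (0.29, adjusted p = 0.00406), without the 3 arrays with cornified transcripts (0.34, adjusted p = 0.00562) and without wildtype 1 and wildtype 4 (0.36, adjusted p = 0.000266). In the last of these, collagens (0.13, adjusted p = 0.0138) and proteoglycans (0.16, adjusted p = 0.0463) passed as well.

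Keratocyte markers, taken as genes of the resting stromal cell, fell by a mean of -0.35 (camera adjusted p = 0.0388, and adjusted p = 0.522 with an estimated correlation), with 16 of 22 members lower. Of the 22 members, 13 are in another list too, so the fall need not be particular to keratocytes. Keratocan (Kera) was 11.52 ± 0.44 against 12.07 ± 0.69, lumican (Lum) 12.07 ± 0.21 against 12.41 ± 0.47 and decorin (Dcn) 12.63 ± 0.05 against 12.97 ± 0.29 (limma adjusted p = 0.796, 0.815 and 0.726). Wildtype 4 had the highest Kera and Lum signals (8110 and 8788). The other wildtype arrays (2538 to 4329 and 4350 to 4801) overlapped the TGFB arrays (2073 to 4154 and 3728 to 4965). Dcn signals did not overlap, at 6078 to 6594 in TGFB and 6764 to 10642 in wildtype arrays. The prostaglandin synthase Ptgds, which the pigment list also holds, had a difference of -1.67 (SE 0.57) and Aldh1a1 -1.07 (SE 0.43). Corneal endothelial markers fell by -0.29 (adjusted p = 0.0388, and adjusted p = 0.585 with an estimated correlation), with 14 of 16 members lower, led by the bicarbonate transporter Slc4a4 (-1.06, SE 0.41). The keratocyte call ended without TGFB 1, TGFB 2, wildtype 1 or wildtype 4 (adjusted p from 0.0974 to 0.187), with a shift of -0.22 without wildtype 1. The endothelial call ended without TGFB 1, TGFB 2, wildtype 1, wildtype 3 or wildtype 4 (adjusted p from 0.0526 to 0.307), with shifts of -0.16 without TGFB 2 and -0.18 without wildtype 1. At its extremes the endothelial list followed the pigment list, with the lowest means in TGFB 1 and TGFB 2 (8.39 and 8.15) and the highest in wildtype 1 and wildtype 3 (9.15 and 8.91). Between them the order differed. Wildtype 2 (8.55) lay below TGFB 3 and TGFB 4 (8.84 and 8.79) in the endothelial list, but above them in the pigment list (8.59 against 8.29 and 8.19). With the pigment list mean as a covariate the direction of the endothelial list turned to 0.10 (adjusted p = 0.429), and the keratocyte list came to -0.020 (adjusted p = 0.502). That covariate differed between the groups itself (7.76 ± 0.61 in TGFB, 8.97 ± 0.77 in wildtype arrays). It also shares Ptgds with the keratocyte list, so these changes show no cause.

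Inflammatory cytokine, chemokine and prostaglandin genes rose by 0.25 as a list (camera adjusted p = 0.0304, and adjusted p = 0.562 with an estimated correlation), with 24 of 37 members higher. The epithelial chemokine Cxcl14 was 8.99 ± 0.75 in TGFB and 7.01 ± 0.85 in wildtype corneas (adjusted p = 0.623). The neutrophil chemokine Cxcl5 had a difference of 1.42 (SE 0.37), the adhesion molecule Icam1 0.66 (SE 0.19) and the alarmin Il33 -0.67 (SE 0.19). The call ended without TGFB 3, TGFB 4, wildtype 2 or wildtype 3 (adjusted p from 0.0649 to 0.175). Interferon-response genes fell by -0.19 (adjusted p = 0.0388, and adjusted p = 0.687 with an estimated correlation), with 17 of 24 members lower, and Xaf1 had a difference of -0.66 (SE 0.19). The shift of the interferon-response list came to -0.016 without wildtype 1 (adjusted p = 0.925), and its call also ended without TGFB 1, TGFB 3 or TGFB 4 (adjusted p from 0.0502 to 0.122). With the pigment list mean as a covariate the list shift turned to 0.049 (adjusted p = 0.757). Leukocyte and antigen presentation markers did not pass (mean 0.048, adjusted p = 0.440). Macrophage genes Adgre1 (-0.90, SE 0.25) and Cd163 (-1.15, SE 0.37) and the MHC class II gene H2-Ab1 (1.07, SE 0.41) went different ways. Vessel markers gave -0.19 (adjusted p = 0.118), with Cldn5 at -0.71 (SE 0.22), and angiogenic factors 0.0057 (adjusted p = 0.766), with adrenomedullin Adm at 1.08 (SE 0.31) and Sema3c at -0.81 (SE 0.19). Leukocyte (0.18, adjusted p = 0.0143) and vessel markers (-0.32, adjusted p = 0.00996) passed without wildtype 4, but leukocyte markers turned to -0.10 without wildtype 3 (adjusted p = 0.469) and vessel markers came to -0.063 without wildtype 1 (adjusted p = 0.923). Leukocyte markers also passed with array weights (0.15, adjusted p = 0.0384) and without wildtype 1 and wildtype 4 (0.30, adjusted p = 6.85e-06).

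Genes of the pigmented and neural eye were the most strongly lowered of the called lists, while lens genes, not called, fell by about as much as retina genes (-0.84). Pigment cell, iris and ciliary body genes fell by -1.21, with 15 of 16 members lower (camera adjusted p = 2.67e-06, and adjusted p = 0.522 with an estimated correlation). The melanocyte genes Oca2 (-2.71, SE 0.66), Mlana (-2.56, SE 0.76), Trpm1 (-1.88, SE 0.56) and Tyrp1 (-1.70, SE 0.54) passed when adjusted over the list alone. The list mean was lower than the wildtype mean in 4 of 4 TGFB arrays, and the exact permutation p was 0.0857 (adjusted 0.413). Retina genes fell by -0.84, with 16 of 19 members lower (adjusted p = 5.58e-05, and adjusted p = 0.522 with an estimated correlation). The photoreceptor arrestin Sag had signals of 29.0 to 44.2 in TGFB arrays and of 1892, 237, 226 and 30.1 in wildtype arrays, and Rlbp1 and Guca1a had differences of -1.92 (SE 0.74) and -0.85 (SE 0.18). Both calls held in 9 other processing settings and without any single array, but without wildtype 1 the retina shift was -0.44 (adjusted p = 0.0134). Besides the estimated correlation, neither list passed fry (adjusted p = 0.505 and 0.528). The adjusted p of the exact permutation test was 0.413 for both, in a test that passes only if many lists reach its smallest p together. The retina list turned to 0.051 (camera adjusted p = 0.731) with the pigment list mean as a covariate. Lens genes varied more within groups than between them (6.90 ± 2.18 against 7.74 ± 2.19, adjusted p = 0.105), and the lens list passed without TGFB 3, TGFB 4, wildtype 2 or wildtype 4 (adjusted p from 0.000205 to 0.0393), and with every probe set as its own unit (adjusted p = 0.0194), but its shift was 0.032 without wildtype 3 (adjusted p = 0.666).

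Skeletal muscle genes fell by -0.45 (camera adjusted p = 0.0422, and adjusted p = 0.687 with an estimated correlation), with 20 of 23 members lower, led by myoglobin Mb (-1.95, SE 0.66) and parvalbumin Pvalb (-1.76, SE 0.68). That call ended without TGFB 2, TGFB 4, wildtype 1 or wildtype 2 (adjusted p from 0.123 to 0.764). The shift was -0.28 without TGFB 4, -0.23 without wildtype 1 and -0.71 without wildtype 4. Nerve and Schwann cell genes fell by -0.29 (adjusted p = 0.0490, and adjusted p = 0.522 with an estimated correlation), with 12 of 17 members lower and S100b at -1.22 (SE 0.44). They lost the call without TGFB 1, TGFB 2, TGFB 3, wildtype 1 or wildtype 2 (adjusted p from 0.0649 to 0.175), and their direction turned to 0.083 (adjusted p = 0.957) with the pigment list mean as a covariate. The nerve shift was -0.17 without wildtype 1 and -0.45 without wildtype 4. Red blood cell genes did not pass (mean 0.039, in the direction opposite to the camera test, adjusted p = 0.681). That mean ran from -0.19 without TGFB 3 to 0.25 without TGFB 2. Lacrimal, meibomian and fat genes did not pass either (0.24, adjusted p = 0.0847), except without TGFB 4 (0.32, adjusted p = 0.0193), and came to 0.12 without TGFB 2.

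Immediate-early and heat-shock genes rose by 0.37, with 20 of 24 members higher (camera adjusted p = 5.58e-05, and adjusted p = 0.278 with an estimated correlation). Cells switch on immediate-early genes within minutes of a stimulus, but the list also names heat-shock genes and Cirbp and Rbm3. The list mean was 8.56 ± 0.14 in TGFB and 8.19 ± 0.16 in wildtype arrays and lay above the wildtype mean in 4 of 4 TGFB arrays (exact permutation p = 0.0571, adjusted 0.413). Within each group its highest means were in the arrays with cornified epidermis transcripts, TGFB 1 and TGFB 2 (8.72 and 8.60, against 8.38 and 8.53) and wildtype 2 (8.40, against 8.04 to 8.21). Without these 3 arrays the list was higher by 0.35 (camera adjusted p = 0.000431), and by 0.30 with the cornified score as a covariate (adjusted p = 0.000117). Egr2 had a log2 difference of 1.37 (SE 0.29), Fos 0.78 (SE 0.24), Ier2 0.58 (SE 0.23) and Egr1 0.51 (SE 0.23). Mitochondrial respiratory chain genes fell by -0.14, a small shift carried by 26 of 30 members (adjusted p = 0.00237, and adjusted p = 0.522 with an estimated correlation). Succinate dehydrogenase subunit Sdhb was 11.38 ± 0.06 against 11.67 ± 0.05. Both lists kept their call in 9 other processing settings and without any single array, but neither passed fry (adjusted p = 0.239 and 0.265). The adjusted p of the exact permutation test was 0.413 for both, which decides little, since that test passes only if many lists reach its smallest p together. The mitochondrial call was also lost with the pigment list mean as a covariate, without the 3 arrays with cornified transcripts, and without wildtype 1 and wildtype 4 (adjusted p = 0.0655, 0.0906 and 0.0818). IGF and WNT pathway genes fell by -0.16 (adjusted p = 0.0388, and adjusted p = 0.522 with an estimated correlation), with 25 of 34 members lower, among them the WNT antagonist Dkk2 (-1.13, SE 0.25) and Igfbp6 (-1.08, SE 0.29). The ligand gene Wnt2 was 5.85 ± 0.27 in TGFB and 6.85 ± 0.79 in wildtype corneas. That call held only without TGFB 1 and without wildtype 4 and ended without each of the other 6 arrays (adjusted p from 0.0517 to 0.119).

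Cell cycle genes (-0.077, adjusted p = 0.686), cytosolic ribosomal protein genes (-0.036, adjusted p = 0.868), oxidative stress and xenobiotic genes (-0.23, adjusted p = 0.196) and cartilage and bone genes (0.24, adjusted p = 0.215) did not pass camera. Cdk1 had a difference of -0.43 (SE 0.26), Rplp0 -0.087 (SE 0.22), the glutathione transferase Gsta4 -1.32 (SE 0.43) and chondromodulin Cnmd -0.95 (SE 0.29). The oxidative stress list ran from -0.32 without wildtype 4 to -0.14 without wildtype 1 (camera adjusted p = 0.159 and 0.495). Without wildtype 4, ribosomal protein genes turned to 0.15 (adjusted p = 0.000496), cartilage genes passed at 0.41 (adjusted p = 0.0151) and cell cycle genes at -0.27 (adjusted p = 0.00915). Cell cycle genes also passed without TGFB 2 (adjusted p = 0.00597) but turned to 0.068 without wildtype 2 (adjusted p = 0.267), where cartilage genes came to 0.13 (adjusted p = 0.701). With array weights, cell cycle genes (-0.34, adjusted p = 0.000322) and cartilage genes (0.44, adjusted p = 0.0116) passed. Both lists passed too with the cornified score as a covariate (adjusted p = 0.00110 and 0.0128) and without wildtype 1 and wildtype 4 (adjusted p = 8.76e-07 and 0.000524).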

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

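The tests of arrays that stand apart were fixed as a rule, while the tests of carried-over tissue and RNA decay and the counts of splits for single genes were chosen after the results were seen. Among 370 groups of 4 arrays tested for an array far from the other three, 22 had one, where chance gives about 18 at 1 in 20.

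Wildtype 4, the array with the high 3'/5' ratio, stood apart for 7 genes. It was low for Fmo1 (8.44, others 8.95 to 9.05), Myh11 (5.44, others 8.65 to 9.02), Sema3c (10.05, others 10.80 to 10.86) and Wnt2 (5.66, others 7.21 to 7.31). It was high for Mmp9 (6.17, others 4.75 to 4.85), Matn3 (7.34, others 5.18 to 5.44) and Lum (13.10, others 12.09 to 12.23). Wildtype 1 stood apart in the interferon-response list mean (7.15, others 6.37 to 6.49), in Pvalb (9.48, others 6.03 to 6.52), Prol1 (4.08, others 4.64 to 4.67), Atp5j (11.85, others 11.73 to 11.74) and Ndufa4 (11.30, others 10.81 to 10.87). Serpinb2 was high in wildtype 2 (7.57, others 4.52 to 4.79) and Cxcl5 low in wildtype 3 (4.03, others 4.56 to 4.62).

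Among the TGFB arrays, TGFB 1 was low for Krt12 (8.25, others 11.77 to 12.16) and for the oxidative stress list mean (8.23, others 8.46 to 8.50). TGFB 2 was low for Tgfb3 (8.38, others 9.03 to 9.12) and Cxcl5 (4.63, others 6.22 to 6.39) and high for Cd163 (5.88, others 4.78 to 4.96). TGFB 3 was high for Pvalb (5.74, others 5.12 to 5.21), and TGFB 4 for Actn1 (11.02, others 10.56 to 10.57) and Icam1 (9.08, others 8.47 to 8.54).

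Chance as the source of the differences was weighed with the 35 splits of the 8 arrays into 4 and 4. The real split gave 0 adjusted calls, a count that all 35 splits reach by definition, so that comparison decides nothing; the highest other split gave 6. The real 1288 genes at an unadjusted p were reached or passed by 11 of 35 splits, with up to 2852 in another split. The 15 lists of the real split were reached or passed by 4 of 35, with up to 19 in another, and no split gave fewer than 4. Chance can therefore not be excluded for the unadjusted count or the list count, and splits with more than the real count by a wide margin point to a structure of the arrays other than the groups.

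The lower pigment and retina genes were weighed against dissection, RNA quality and biology. RNA decay in wildtype 4 is argued against as the whole cause, since that array had the lowest pigment list mean of the wildtype arrays (8.09, others 8.59 to 9.77). Leaving it out could therefore only enlarge the shift, to -1.51 (SE over arrays 0.46), and adds no separate evidence. Iris, ciliary body and retina carried over in differing amounts stays open and is consistent with the range of the pigment list mean within the 4 wildtype arrays, 1.68, which is larger than the difference of 1.21 between groups. Of the 16 measured pigment list genes, 13 lay above the median gene and 1 is in another list, and abundant Dct, chosen after its values were seen, had signals of 1354 to 5984 in TGFB and 4673 to 8080 in wildtype arrays. Fewer such cells in TGF-beta overexpressing eyes cannot be told apart from dissection (exact permutation p = 0.0857), because no label records how the corneas were cut.

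The higher epithelial junction genes were weighed against skin and against a larger epithelial share. Skin carried over with the cornea cannot be told apart: without TGFB 1, TGFB 2 and wildtype 2, which hold the cornified transcripts, the list was higher by 0.26 (SE over arrays 0.15), and by 0.17 (SE 0.12) with the cornified score as a covariate. Both shifts passed camera with the preset correlation (adjusted p = 0.00449 and 0.0105), but both are under 2 SE, a bound set after the values were seen. The list mean also rose with the cornified score across arrays (0.098 per log2 unit, SE 0.022), as carried-over skin would give. A larger share of corneal epithelium also stays open, since the corneal epithelial list gave 0.046 with members going both ways, Krt14 at 1.10 and Krt12 at -0.34. That list ran from -0.22 to 0.19 over single arrays left out, and passed at 0.17 without the same 3 arrays and at 0.42 with the pigment covariate. An effect of the TGF-beta overexpression on the epithelium remains among the open explanations as untested. Of the 32 measured junction list genes, 9 are in another list and 24 lay above the median gene.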

How the results depend on the processing

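All settings with covariates, with 2 or 3 arrays left out, the counts at an unadjusted p under each alternative and the separation with 1 array left out were chosen after the data were seen. The other settings in this section were planned. The count of genes higher in TGFB corneas was 0 in all 25 settings tried, and the count of genes lower was 0 in 23 of 25, with 2 (Ces1d and Pi16, chosen after their values were seen) without wildtype 4 and 3 (Ces1d, Sag and Rgr, the last chosen in the same way) without wildtype 1 and wildtype 4. Leaving out single arrays gave 0 higher and 0 to 2 lower genes, 326 to 810 higher and 513 to 1497 lower genes at an unadjusted p, and 9 to 21 lists. At an unadjusted p, every probe set as its own unit gave 1218 higher and 1423 lower, array weights 831 and 1317, the pigment list mean as a covariate 285 and 313, and the arrays without TGFB 1, TGFB 2 and wildtype 2 gave 472 lower. Of the 31 lists, 15 passed at first, 9 with median centring and 0 with an estimated correlation. With the pigment covariate 6 of 30 passed, 2 of them among the 15 (TGF-beta target and immediate-early genes). The cause was not tested for any of these changes. Over the planned settings other than the estimated correlation, 434 of 527 list values kept their side of the threshold with or without their sign, and 393 kept both. The sign of the mean changed in 42 values, all in 10 of the lists not called at first. Of the rest, 71 lost and 20 gained the call, and 2 turned in the direction of the camera test (the interferon list without wildtype 1, with a mean still below 0, and ribosomal protein genes without wildtype 4); 4 of the 15 lists held in all of these (pigment, retina, immediate-early and mitochondrial genes). The interferon list ran from -0.27 to -0.016 over single arrays left out and was 0.010 without wildtype 1 and wildtype 4, and ribosomal protein genes ran from -0.14 to 0.15 and were 0.076. With the pigment covariate the retina list came to 0.051, corneal endothelial markers to 0.10, interferon genes to 0.049 and nerve genes to 0.083, none past the threshold. The lists that gained a camera call were lens genes (2.21, adjusted p = 7.84e-10), red blood cell genes (0.83, adjusted p = 0.0138), ribosomal protein genes (-0.31, adjusted p = 1.83e-05) and corneal epithelial markers (0.42, adjusted p = 0.00283). This covariate differed between the groups itself, so these changes show no cause. The separation of arrays was tested in only some settings, and its exact permutation p stayed above 0.05 in each of them. That p was 0.371 both with quantile normalization and with the filter on probe set means. With 1 array left out it ran from 0.200 to 0.943. The separation was not tested in the other settings. Robust eBayes has no counterpart in the list test, which was not run for it. No paired analysis was possible because the labels give no litter or shared number. Dim genes near the added 16 are limited by signal over background.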

Other observations

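The tests of carried-over tissue were chosen after the result was seen, and the test of neighbouring genes below was set up before its result was known. Growth and muscle transcripts were abundant on all 8 arrays; these genes were chosen after their values were seen. The fetal growth factor Igf2 had signals from 5933 in wildtype 1 to 8148 in wildtype 4, a spread of 1.37 times. Perinatal myosin Myh8 ran from 2065 in TGFB 4 to 7541 in wildtype 2, and the fast myosin light chain Mylpf from 5925 to 10262. The proliferation marker Mki67 lay between 850.1 and 1999. The labels give no age, so these values stand without a stage.

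A hypothesis was that a chromosome segment carried with the transgene could show as a run of affected neighbouring genes. Among 18020 placed genes, the densest stretch of 20 neighbours held 3 genes at an unadjusted p under 0.01 (Pnoc, Ephx2 and Stmn4, on chromosome 14, chosen after their values were seen). As many or more were found in 16 of 35 splits, the real one included, with up to 16 in another split. The splits with the highest counts put TGFB 1, TGFB 2 and wildtype 2, the arrays with cornified transcripts, into one group. The splits therefore also carry differences in tissue and are no clean reference for a segment. The densest stretch did not stand out among them, but the test cannot decide whether a segment was carried. The test also says nothing about a segment with 1 or 2 such genes.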
